A study of Mus musculus with 18 samples.

How the data were processed

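Polyadenylated RNA from mouse hippocampus was measured by sequencing in 3 kinds of genetically modified mice and in nontransgenic controls kept for each of them. In the first kind, the microRNA genes Mir132 and Mir212 are deleted in excitatory forebrain neurons by a Cre recombinase driven from the CaMKII promoter, and this is called the deletion below. In the other kinds, a tetracycline transactivator (tTA) drives a transgene for miR-132 or for miR-212, called tTA::miR132 and tTA::miR212. As nontransgenic animals, the controls lack the recombinase or the transactivator as well as the change in microRNA. An effect of either driver can therefore not be told apart from that of the microRNA in any comparison. Per the labels' protocols and the series design text, total hippocampal RNA was extracted with TRIzol, polyadenylated RNA was taken from it with oligo(dT) beads, cDNA of 6 animals was pooled into 3 replicates for each group, libraries followed the Illumina TruSeq guide and were read on a Genome Analyzer II, and reads were aligned with Bowtie 0.12.7 to the UCSC build mm9 and handled with custom R scripts. The design text also names abundances from Cufflinks 1.2, a unit that is not used here. The counting tool, the gene annotation and the filter on genes are not given in the sources used here. The test behind the authors' p-values is given only by the deposited names, which hold DESeq2 for tTA::miR212 and PairWiseCommon for the deletion and tTA::miR132. The authors' q-values of these comparisons may therefore come from unlike tests.

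The labels list 18 samples in 6 groups of 3. The tables analysed here hold 14 libraries, because the tables of the deletion and of tTA::miR132 have 2 libraries per group and that of tTA::miR212 has 3. The third library of those 4 groups is not analysed here. Column names give a group and a number while the sample labels give letters, so a library is a numbered member of its group and was tied to no single sample. Libraries are called library 1, 2 or 3 of a group by the number in the column name. Replicates are described as pools of animals, so p-values of single genes measure the spread between libraries taken as separate pools.

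The deposited read counts are whole numbers per gene or transcript, not normalized, per the file headers and the values. The tables list 10541 RefSeq genes for the deletion and 10799 for tTA::miR132, each with 1 entry per gene symbol. The tTA::miR212 table lists 11706 Ensembl transcripts whose reads overlap within a gene. For each of its 4618 gene symbols the transcript with the highest mean count was kept (2555 symbols had more than 1), and all transcripts were tested as an alternative. The tables of the deletion and of tTA::miR132 list no gene on chromosome X, while 464 transcripts on it are listed for tTA::miR212. Beside the counts, the authors gave a mean signal over all libraries, a difference and a signed fold change of the group means (scores), an absolute fold ratio, and p-values and q-values, per the file headers. A further 14 columns of normalized values per library were not used. The authors' difference had the sign of control minus deletion for 10301 genes of the deletion table and the opposite sign for 226, so it was turned. These columns of the authors' comparison were read only to count q-values and to set them beside the new tests.

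Total counts were 8190899 to 9702801 in the 4 libraries of the deletion table, 8301385 to 14772907 in the tTA::miR132 table and 3140536 to 3739682 in the tTA::miR212 table, where keeping 1 transcript per gene left 1299369 to 1544923. Because the tables list genes that passed a filter of the authors, these are not full sequencing depths. Counts come from amplified reads without molecular identifiers, so counting error alone understates the error of a value. Counts of replicate libraries differed by more than sampling noise in each pair of every table. The lowest chi-square per degree of freedom was 1.388, between control libraries 1 and 2 of the tTA::miR212 table. Amplification could also give such an excess, so this does not show that the libraries are separate pools. Every library was counted as its own sample, following the replicates of the labels.

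Each comparison was fitted within its own table in R 4.3.3 with edgeR 4.0.16, using the quasi-likelihood test with TMM factors, filterByExpr, robust estimation and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. CPM values were computed from the counts with the TMM library sizes. The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Tests on 26 lists of genes (reported microRNA targets, neuronal signalling and synapse genes, markers of hippocampal and other brain cell types, and metabolic or stress pathways) used camera of limma 3.58.1 on the same data with an inter-gene correlation of 0.01, adjusted over the lists of a comparison. The alternatives to it were an estimated correlation and fry. An estimated correlation also limits the degrees of freedom to those left between libraries (2 for the deletion, 2 for tTA::miR132 and 4 for tTA::miR212). With the set correlation of 0.01 they come from the number of genes, which then act as replicates. A list was tested when at least 3 members were measured, which left out the red blood cell list in each table and, for tTA::miR212, also the choroid plexus, endothelial, ependymal, meningeal, oligodendrocyte precursor and thalamus lists, so that 25, 25 and 19 lists were tested. The result on 1 gene and the result on 1 list are not reported here. The rule for named genes takes the passing genes with the largest change whose groups do not overlap, and, where fewer than 5 genes pass in a direction, the 5 with the smallest unadjusted p in it, and up to 4 members per list by the same measure. In the report, members ranked first are those with the smallest unadjusted p. Other genes named as calls of an alternative were chosen after their values were seen. For a gene at 0 in each library of a group, the fold is a lower bound against a floor of 3 counts over the group, which covers counting error only.

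MiR-132-3p and miR-212-3p share a seed. Their target sites are the 7-base site GACTGTT and the 8-base site GACTGTTA, and genes were called sites when their longest 3' UTR in the mouse annotation of the same build held either. A 3' UTR was annotated for 98.6% of the genes of the deletion table, 98.6% for tTA::miR132 and 95.4% for tTA::miR212. Genes with and without a site were compared with camera, and 299 control 7-mers of the same base composition gave the differences that arise without a shared seed, within tertiles of 3' UTR length. Fold changes of a pair of comparisons were correlated across genes, and shared calls were tested with Fisher's exact test, two-sided. Splits of the libraries into groups of the same size gave the correlations that arise without the genotypes, computed on differences of mean log2 CPM for real groups and splits alike. The tables allowed 9 or 30 pairs of such splits instead of the intended larger number, because 2 libraries per group allow few. The smallest share possible was 0.111 with 9 pairs and 0.0333 with 30.

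Scripts were tested on simulated data with 200 changed genes, drawn from the means, sizes and fitted dispersions of each table. Of genes changed 2-, 4- or 8-fold, edgeR recovered 9.38%, 40.3% and 50.8% at the size and spread of the deletion table (10487 genes), 6.15%, 38.8% and 63.1% for tTA::miR132 (10734 genes) and 98.5%, 100% and 100% for tTA::miR212 (4618 genes). Among simulated calls by DESeq2, 73 of 153 in the deletion table, 49 of 148 for tTA::miR132 and 3 of 201 for tTA::miR212 were genes that had not been changed. For edgeR these were 9 of 75, 2 of 73 and 10 of 209. A shift of -0.20 (log2) was also simulated in the genes with a seed site. It was recovered by camera as -0.22 (adjusted p = 0.0107 over the 3 comparisons), -0.21 (adjusted p = 0.00162) and -0.20 (adjusted p = 1.41e-40) in the order deletion, tTA::miR132 and tTA::miR212. Simulated genes were independent and simulated libraries alike in quality. In the real data deletion library 1 differed from the others and members of some lists were correlated. Recovery in the real data may therefore be lower than simulated.

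Alternatives were DESeq2 1.42.0, limma-voom, library size alone, upper-quartile factors, no filter, a mean of at least 50 counts, the library number as a block, and leaving out each library. Alternatives chosen after seeing the data were the fit of all transcripts, a joint fit of the 8 libraries of both RefSeq tables (with and without deletion library 1 and tTA::miR132 control library 2, which have the most genes at 0 in their tables), an estimated correlation for the seed test and for the lists with each library left out or with the block, the block for the lists, and bounds with each library left out. A single fit of all libraries and the test of the tTA::miR132 effect against the tTA::miR212 effect were not run, because the tables use different gene models.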

Results

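Hippocampal transcripts were counted in 14 libraries to ask what the loss or gain of miR-132 and miR-212 does to gene expression in the adult mouse hippocampus, a brain region needed for memory. Both microRNAs are short RNAs made from neighbouring genes that lower the level or translation of messages carrying their seed site. The deletion was compared with its controls in 2 libraries each, tTA::miR132 with its controls in 2 each, and tTA::miR212 with its controls in 3 each. The deletion libraries held 9408155 and 9702801 counts against 9432812 and 8190899 in controls. The tTA::miR132 libraries held 14772907 and 8772987 against 9899963 and 8301385. The tTA::miR212 libraries held 3146667, 3739682 and 3619791 against 3279620, 3140536 and 3173371, counted over overlapping transcripts.

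Mir132 lies on chromosome 11 at 74987167 to 74987267 and Mir212 at 74986890 to 74986980, both on the plus strand (mouse build mm9). Neither microRNA gene is among the genes of the tables, so the targeted genes do not check the labels here. Of the neighbouring protein-coding genes, Smg6 (74739374 to 74977950) had 50 and 397 counts in deletion libraries 1 and 2 against 335 and 383 in controls. Hic1 (74978067 to 74983757) had 0 and 108 against 34 and 12.

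Libraries of the RefSeq tables were far from equally complete. Deletion library 1 had 1047 of 10541 genes at 0 (9.93%) against 120 in deletion library 2 and 90 and 73 in controls. Its correlation with the other libraries of its table across genes (log2 CPM, genes not being independent replicates) was 0.63 to 0.66, while the other pairs reached 0.88 to 0.90. In the tTA::miR132 table, control library 2 had 485 genes at 0 and transgenic library 1 had 262, against 155 and 92 in the others. The biological coefficient of variation was 74.2% in the deletion table, 60.7% for tTA::miR132 and 8.58% for tTA::miR212.

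**Figure D1:**
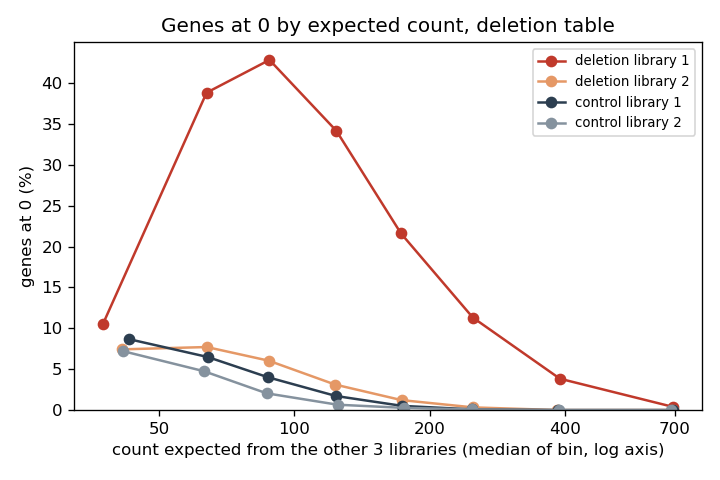
Percent of genes at 0 (vertical axis) in each library of the deletion table against the count expected from the other 3 libraries (horizontal log axis, median of each bin of genes). In deletion library 1, 34.1% of genes expected at 100 to 150 counts were at 0, against 3.12% in deletion library 2 and 1.72% and 0.655% in controls.

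The first question was which transcripts differ when miR-132 and miR-212 are deleted from excitatory neurons. Transcripts of the choroid plexus, the epithelium that makes cerebrospinal fluid and lies next to the hippocampus, were lower in the deletion libraries. The deletion is not directed at this epithelium. Ttr, which encodes the thyroid hormone carrier transthyretin (NM_013697, chromosome 18, 20823751 to 20832825, plus strand), had 1083 ± 805 CPM (SD, n = 2) against 4530 ± 312 in controls (n = 2), a log2 fold change of -2.06 (SE 0.52), or -1.45 without deletion library 1 and -3.13 without library 2. Kl, the anti-ageing factor klotho, had 13.6 ± 4.35 against 56.6 ± 34.5 CPM, and Col8a1, a collagen, 3.24 ± 1.15 against 29.3 ± 10.8 CPM. The choroid plexus transcription factor Otx2 had no count in either deletion library against 122 and 110 counts in controls. By counting error alone this was at least 82.6-fold lower over the group (43.0-fold without deletion library 1, 39.6-fold without library 2, which lowers the counts behind the floor). Of genes expected at 100 to 150 counts, 34.1% were at 0 in deletion library 1 and 3.12% in library 2. The zeros therefore do not bound the expression of Otx2.

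As a list, the choroid plexus genes fell against all other genes in the deletion. All 13 measured members of the 15 listed lay below 0, 11 of them with both deletion libraries below both controls. Chance gives 16.7% in a direction per gene, but the members varied together (estimated correlation 0.697) and are not independent. The median log2 fold change was -2.06, also with Otx2 at its bound (camera of limma, adjusted p = 3.55e-11). With the correlation between members estimated from these libraries the call was lost (adjusted p = 0.963 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. Without deletion library 1 the median was -1.33 (adjusted p = 7.54e-10), and without deletion library 2 it was -9.87 (adjusted p = 1.47e-08), a fitted value that rests on genes at 0 in library 1 and is no measured fold. Without control library 2 the median was -1.45. Leaving out any single library kept the list below the threshold, at adjusted p from 5.24e-18 to 1.47e-08, but none of these calls held with an estimated correlation (adjusted p = 0.929 to 0.997 with an estimated correlation).

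**Figure D2:**
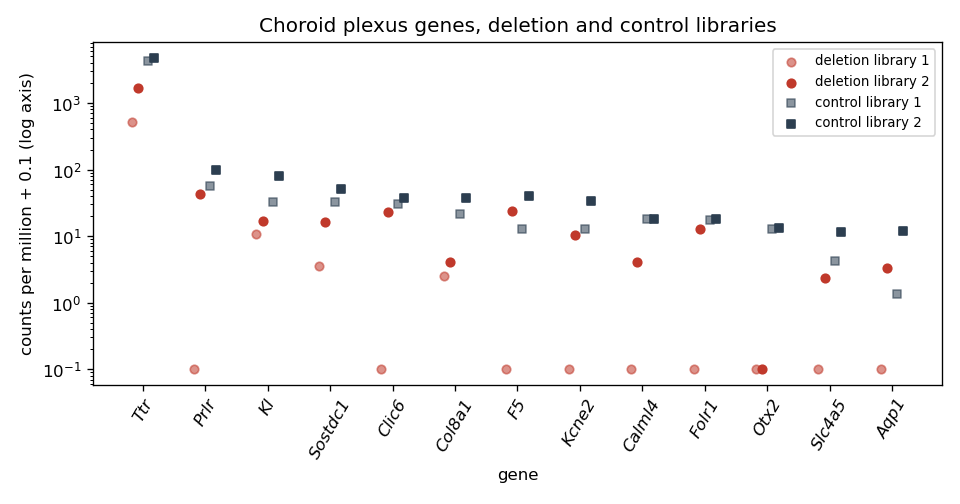
CPM plus 0.1 (vertical log axis) of the 13 measured choroid plexus genes (horizontal axis) in the deletion libraries (circles) and control libraries (squares), 1 point per library. Ttr lay at 514 and 1652 CPM in the deletion libraries and at 4309 and 4750 in controls.

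Genes with the smallest p outside this list were Tmem25, an immunoglobulin-type membrane protein gene (log2 fold change 1.33, SE 0.36), Coro7 (1.41), the collagen gene Col19a1 (1.40), Eid2 (1.07) and the histone methyltransferase gene Ehmt2 (1.01), all higher in both deletion libraries. The lower ones beside Ttr were 1500015O10Rik (-1.63), Exosc9 of the RNA exosome (-1.71), the endoplasmic reticulum chaperone gene Hspa5 (-0.69) and Enpp2, which makes lysophosphatidic acid (-0.94). None passed adjustment by edgeR (adjusted p = 0.999 each). The choroid plexus list was short and fixed beforehand, so genes outside it may still follow its members, which was not tested. Reported targets of the microRNAs lay above 0 in 12 of 17 measured members, with a median of 0.12 (camera, adjusted p = 0.467). Hbegf, a growth factor gene among them, had a log2 fold change of 2.94 (SE 1.02) that came from 144 CPM in library 1, against 19.2 in library 2 and 7.87 and 13.4 in controls. In the list of glutamate receptors and postsynaptic scaffolds, Nlgn2 had 0.86 (SE 0.33) and Dlg4, which encodes the scaffold PSD-95, 0.74 (SE 0.30). The median of that list was 0.17 (camera, adjusted p = 0.607).

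The remaining lists of neurons, glia, vessels, energy metabolism and stress did not pass in the deletion (24 of 25 lists, adjusted p 0.467 to 0.959). Median, mean and test differed in sign in 11 of them, which were the immediate early, glutamate receptor, CREB, CA1, CA2 and CA3, dentate granule, microglia, meningeal, thalamus, ribosomal and glucocorticoid lists. The oxidative phosphorylation genes turned with the library left out. They lay lower without deletion library 1 (adjusted p = 6.13e-06) and higher without deletion library 2 (adjusted p = 0.0367) or control library 1 (adjusted p = 0.0276). The ribosomal protein genes lay lower without deletion library 1 (adjusted p = 0.00085). None of these passed with an estimated correlation (adjusted p = 0.929 to 0.997 with an estimated correlation).

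Across 10487 genes, edgeR called 0 at an adjusted p under 0.05, and 88 had an unadjusted p under 0.05. DESeq2 called 5, of which Tmem25, Coro7 and Pstpip1 were higher and 1500015O10Rik and Sfxn4 lower, and limma-voom called 0. The count rested on single libraries. It was 8 without deletion library 1 (Ttr among them, log2 fold change -1.45, adjusted p = 2.09e-11), 1 without control library 1 and 1 without control library 2 (Ttr each time), and 4527 without deletion library 2, where library 1 stood alone against the controls. Groups did not overlap for 32.5% of genes, where chance gives 33.3%. In the authors' deposited table, 5727 of 10541 genes (54.3%) had a q under 0.05. Of the 5723 among them tested here, 39.3% had groups that did not overlap and 88 had an edgeR p under 0.05.

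The next comparison asked which transcripts differ when miR-132 is made in excess. Camk2n1, which encodes an inhibitor of the synaptic kinase CaMKII (NM_025451, chromosome 4, 138011063 to 138016041, plus strand), had 841 ± 7.24 CPM (SD, n = 2) in tTA::miR132 against 1625 ± 142 in controls (n = 2). Its log2 fold change was -0.95 (SE 0.14, edgeR adjusted p = 0.187), while limma-voom (adjusted p = 1.56e-10) and DESeq2 (adjusted p = 2.26e-13) called it. Genes of synaptic vesicles and transmitter release fell as a list. Of its 36 measured members, 29 lay below 0 and 15 had both transgenic libraries below both controls. Chance gives 16.7% per gene, and genes are not independent replicates. The median of the list was -0.17 (camera of limma, adjusted p = 0.000561, or adjusted p = 0.866 with an estimated correlation). The active zone genes Pclo (-0.81, SE 0.25) and Rims1 (-1.86, SE 0.73), the vesicle membrane gene Vamp1 (-0.81, SE 0.33) and Rims3 (-5.25, SE 2.27, from 0 and 9 counts against 26 and 281) ranked first among its members.

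The call on vesicle genes was also lost without control library 1 (adjusted p = 0.0729), and the median was -0.26 without transgenic library 2. No member passed over all genes or adjusted over the list alone. Receptors and scaffolds of the postsynaptic side had a median of -0.18 (20 of 32 below 0, adjusted p = 0.287), among them Dlg1 with -1.19 (SE 0.37) and Dlg2 with 0.83 (SE 0.33). Reported microRNA targets had a median of -0.10 (12 of 19 below 0, adjusted p = 0.654). Mapt, the gene of the microtubule protein tau and a reported target, had 469 ± 39.0 against 656 ± 90.9 CPM (-0.48, SE 0.18). Mef2c, a neuronal transcription factor gene with a seed site that was named after its value was seen, had -0.69 (SE 0.19, edgeR adjusted p = 0.997, DESeq2 adjusted p = 0.00771).

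Other genes with small p in tTA::miR132 were Nnat, an imprinted neuronal gene (500 ± 8.09 against 292 ± 30.1 CPM, 0.77, SE 0.19), the cilium gene Spag6 (4.43), Tcf20 (2.49), Vps13d (2.38) and 2610002I17Rik (5.31), all higher. Strn4 (-0.99, SE 0.23) and Enpp2 (-0.62, SE 0.15) were lower, and Kank4 and Lox had no count in either transgenic library against 160 and 255 and against 32 and 312 counts in controls. By counting error alone they were at least 184-fold and 152-fold lower over the group. Zeros of other origin are not covered by these bounds, and 262 genes were at 0 in transgenic library 1. The bound for Lox rested on control library 2, without which it was 25.6-fold, and was 309-fold without control library 1 and 57.2-fold and 95.1-fold without transgenic library 1 or 2. That for Kank4 was 69.1-fold and 115-fold without transgenic library 1 or 2. Spag6 had 3.80 without transgenic library 1 and 6.36 and 3.65 without control library 1 or 2, and Tcf20 3.36 without control library 1. None passed adjustment over all genes by edgeR (adjusted p = 0.997 each). Spag6 was the only list member to pass adjusted over the list alone (adjusted p = 0.0145), in the ependymal list of 4 genes, whose median of -0.23 and test had opposite signs (adjusted p = 0.506). The other lists had adjusted p of 0.287 to 0.985, and median, mean and test also differed in sign for the CA2 and CA3, microglia, meningeal and striatum lists. The myelin list passed without control library 2 (higher, adjusted p = 0.0422, or adjusted p = 0.935 with an estimated correlation). Choroid plexus genes, marking tissue next to the hippocampus, had a median of -0.40 (7 of 13 below 0, adjusted p = 0.653).

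Across 10734 genes, edgeR called 0 in tTA::miR132 and 303 had an unadjusted p under 0.05. DESeq2 called 39 (15 higher, 24 lower) and limma-voom 2, Camk2n1 and Enpp2. The edgeR count was 111 (94 higher, 17 lower) without control library 1 and 4 without transgenic library 2 (Fzd7, Ift88, Mmp15 and Mtap, all lower). Groups did not overlap for 33.0% of genes, where chance gives 33.3%. In the authors' deposited table, 5731 of 10799 genes (53.1%) had a q under 0.05. Of the 5723 tested here, 41.9% had groups that did not overlap and 290 had an edgeR p under 0.05.

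The third comparison asked the same of miR-212. Glucocorticoid-responsive genes fell in the tTA::miR212 libraries. Sgk1, a kinase gene induced by corticosteroids, had 73.0 ± 16.7 CPM (SD, n = 3) against 110 ± 15.7 in controls (n = 3), and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, 68.6 ± 17.3 against 106 ± 21.1 CPM. Their log2 fold changes were -0.60 and -0.63, and both passed edgeR's test adjusted over the list alone (adjusted p = 0.0127 and adjusted p = 0.0327) but not over all genes (adjusted p = 0.714 and adjusted p = 0.801). Klf9 had -0.16 and Per1, which is also on the immediate early list, -0.27. Of 6 measured members 4 lay below 0, with a median of -0.21 (camera of limma, adjusted p = 0.00781, or adjusted p = 0.545 with an estimated correlation). The call was lost without transgenic library 2 (median -0.07, adjusted p = 0.176) and without control library 2 (adjusted p = 0.0953), and the median was -0.41 without transgenic library 1.

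Dentate granule cell genes also fell in tTA::miR212, with 3 of 3 measured members of the 10 listed below 0 and a median of -0.13 (adjusted p = 0.0146, or adjusted p = 0.545 with an estimated correlation). The list leaned on the desmosome gene Dsp, at 40.6 ± 6.70 against 70.4 ± 6.66 CPM (-0.78), which passed adjusted over the list alone (adjusted p = 0.00334) but not over all genes (adjusted p = 0.714), while the calcium buffer gene Calb1 had -0.13 and the transcription factor gene Prox1 -0.01. This call was lost without transgenic library 1 (median -0.23, adjusted p = 0.221) and without control library 2 (median -0.09, adjusted p = 0.141), and the median was -0.08 without transgenic library 3. The libraries also differed in other ways. Xist, the RNA made from the inactive X chromosome of females, had 3.07, 703 and 130 CPM in transgenic libraries 1, 2 and 3 against 761, 1305 and 1363 in controls (edgeR adjusted p = 0.919), and Ttr had 800, 39.7 and 671 CPM against 780, 713 and 264. The choroid plexus list had too few measured members to be tested there.

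Activity-regulated immediate early genes separated the transgenic libraries from each other. Fos had 166 CPM in library 1 and 28.1 and 17.4 in libraries 2 and 3, around a control mean of 71.7 ± 3.39 (SD, n = 3), and Arc had 802, 243 and 185 CPM against 514, 514 and 430. As a list, 14 of 17 members lay below 0 (median -0.15, camera, adjusted p = 0.0965, or adjusted p = 0.724 with an estimated correlation, which was 0.709). The list passed when transgenic library 1, the only transgenic library above the controls, was left out (lower, adjusted p = 1.43e-31, or adjusted p = 0.0189 with an estimated correlation), and with no other single library left out. Without library 1, Fos (-1.64), Nr4a1 (-1.27), Arc (-1.18), Junb (-1.02), Egr4 (-0.94) and Per1 (-0.66) were among the 18 genes that edgeR then called. Leaving out the library that ran the other way favours lower calls, so these do not show a fall of the group.

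**Figure D3:**
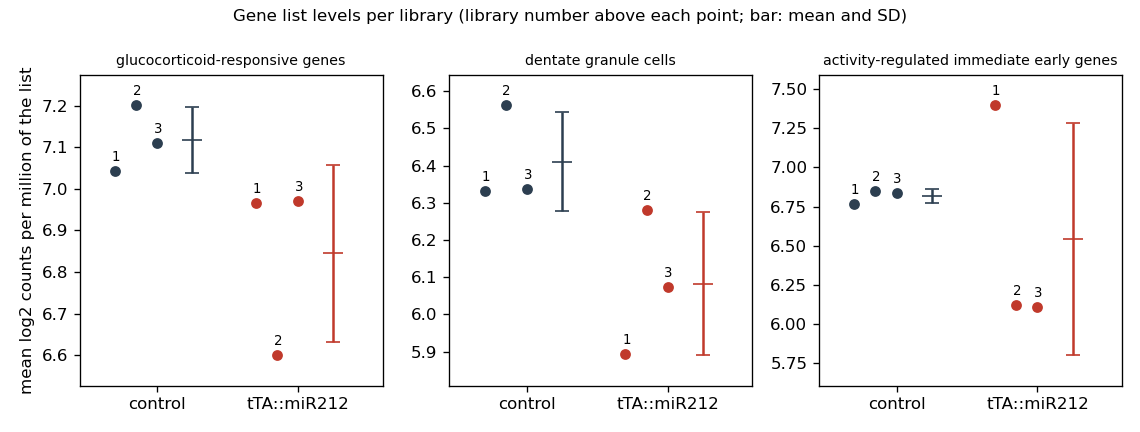
Mean log2 CPM of 3 gene lists (vertical axes) in the libraries of the tTA::miR212 table, numbered points with the mean and SD of each group beside them. The immediate early genes lay at 7.40 in transgenic library 1 and at 6.12 and 6.11 in libraries 2 and 3, against 6.77 to 6.85 in controls.

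Single genes with the smallest p in tTA::miR212 were Ptprn2, a dense-core vesicle phosphatase gene (ENSMUST00000070733, chromosome 12, 117724306 to 118515266, plus strand), at 235.0 ± 15.2 against 345 ± 55.9 CPM (-0.55, SE 0.11, edgeR adjusted p = 0.415), and Lrrn2, a leucine-rich repeat neuronal gene on chromosome 1, at 357 ± 48.9 against 255.0 ± 22.4 CPM (0.49, SE 0.10, adjusted p = 0.46). Hipk4 (-0.52), the calmodulin-binding neurogranin gene Nrgn (-0.33), Cyb561 (-0.45) and the vesicle fusion gene Doc2b (-0.48) were lower in every transgenic library than in every control. C530008M17Rik (0.34), Slc35f1 (0.48), the cell death gene Hrk (0.43) and the intermediate filament gene Synm (0.36) were higher in the same way. Among astrocyte genes, the water channel gene Aqp4 had 0.61 and passed edgeR's test adjusted over the list alone (adjusted p = 0.0439), and Gja1 (0.27, SE 0.09) and Gfap (0.36, SE 0.12) ranked next, in a list with a median of 0.04 (9 of 14 above 0, adjusted p = 0.0965).

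Reported targets of the microRNAs lay above 0 in 12 of 15 members in tTA::miR212 (median 0.10, adjusted p = 0.0965), with Ache, the acetylcholinesterase gene, at 0.39 (SE 0.16). This list passed without transgenic library 2 (adjusted p = 0.00745, or adjusted p = 0.624 with an estimated correlation) and without control library 3 (adjusted p = 0.0322, or adjusted p = 0.546 with an estimated correlation). The synaptic vesicle list passed without control library 1 (lower, adjusted p = 0.0399, or adjusted p = 0.739 with an estimated correlation; median of all libraries -0.06). The 17 lists that did not pass had adjusted p of 0.0965 to 0.997, and median, mean and test differed in sign for the CREB and the CA2 and CA3 lists.

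Across 4618 genes, edgeR called 0 in tTA::miR212 and 260 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each. Without transgenic library 1 edgeR called 18 (6 higher, 12 lower). Groups did not overlap for 11.4% of genes, where chance gives 10%. In the authors' deposited table, 7 of 11706 transcripts had a q under 0.05, of 4 genes tested here, each with groups that did not overlap.

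Genes with a seed site for miR-132 and miR-212 in their 3' UTR were then compared with all other genes. In the deletion, 1388 genes with a site had a median log2 fold change that differed from that of 8955 others by -0.01, with the test, which compares means, leaning the other way (camera of limma, adjusted p = 0.971 over the 3 comparisons). In tTA::miR132 the difference was -0.01 (1409 against 9184 genes, adjusted p = 0.971), and in tTA::miR212 it was 0.02 (701 against 3750 genes, adjusted p = 0.845). Control 7-mers spanned -0.09 to 0.05, -0.05 to 0.05 and -0.02 to 0.02 in the order deletion, tTA::miR132 and tTA::miR212 (95% of 299), all within tertiles of 3' UTR length. Computed in the same way, the differences of the seed were 0.0071, -0.0135 and 0.0082, at percentiles 71.6, 35.5 and 65.2 of them. The sign of the difference in the deletion turned with 8-base sites alone (0.04), within those tertiles and without deletion library 1 (0.04), and was 0.00 without control library 2, and in tTA::miR132 without transgenic library 1 (0.01).

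**Figure D4:**
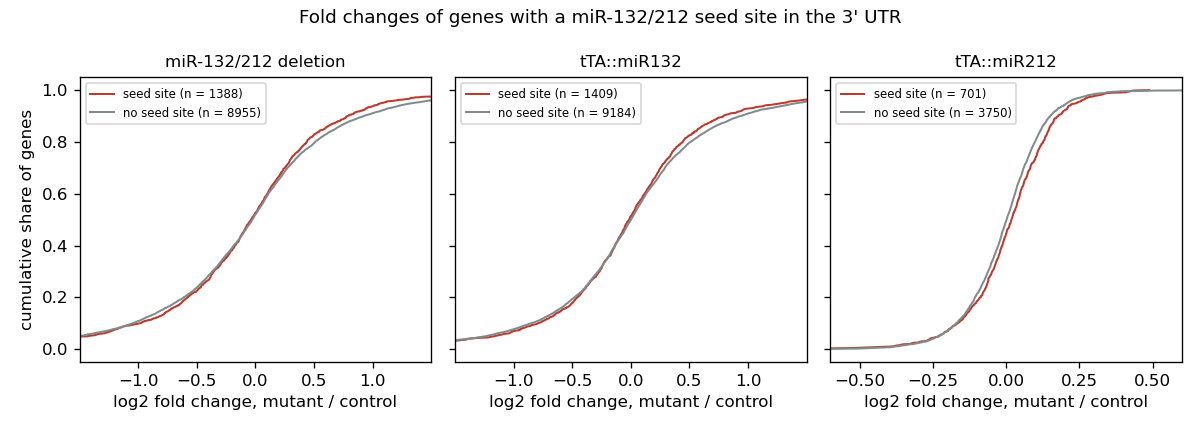
Cumulative share of genes (vertical axis) by log2 fold change of mutant over control (horizontal axis) for genes with and without a seed site in the 3' UTR, in each comparison. The curves of both classes ran close together, with median differences of -0.01 in the deletion, -0.01 in tTA::miR132 and 0.02 in tTA::miR212.

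The last question was whether loss and gain, or both microRNAs, moved the same genes. Across 9980 genes, fold changes in the deletion and in tTA::miR132 had a Pearson r of -0.02 (Spearman -0.01). Splits of the libraries were compared by differences of mean log2 CPM, which gave r = -0.0439 for the real groups, and 6 of 9 pairs of splits gave an absolute r as large as that. Against tTA::miR212, the deletion had r = -0.02 over 4184 genes (Spearman -0.02), or -0.0098 by mean log2 CPM, where 23 of 30 split pairs were as large. The transgenic lines had r = 0.07 over 4197 genes (Spearman 0.07), or 0.054 by mean log2 CPM, where 4 of 30 split pairs were as large (highest other 0.0845). The r of 0.07 was 0.00 without tTA::miR132 control library 1, 0.11 without its control library 2 and 0.03 without tTA::miR212 transgenic library 2. Genes are not independent replicates, and the controls of the comparisons are separate libraries. Camk2n1, which stood out in tTA::miR132, had -0.51 in tTA::miR212 (edgeR adjusted p = 0.919) and -0.04 in the deletion (adjusted p = 0.999). Since edgeR called no gene in any comparison, no called gene was shared. At an unadjusted p under 0.01 no gene was shared either (1 and 22, 1 and 52, and 16 and 53 genes, with 0.0022, 0.0124 and 0.202 shared genes given by independent lists, Fisher's exact test p = 1 each).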

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

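The joint fit behind the differences in this part, the test of Ttr spread, the test of scaling, the test of depth and the test over genes expected above the lowest maximum of the table were chosen only after the result was seen.

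The effect of the deletion and that of tTA::miR132 were set against each other in 1 fit of the 8 libraries of both RefSeq tables, and 3 of 25 gene lists differed between them. Synaptic vesicle genes had a median log2 fold change of 0.11 in the deletion and -0.14 in tTA::miR132 (camera of limma, adjusted p = 8.98e-05), and glutamate receptor and postsynaptic scaffold genes 0.19 and -0.18 (adjusted p = 0.025). Choroid plexus genes had -2.04 and -0.40 (adjusted p = 2.54e-06). None of the 3 differences held with an estimated correlation (adjusted p = 0.549 each with an estimated correlation). Each effect is relative to the controls of its own table, and the joint fit called 0 genes for the difference itself with edgeR (195 with an unadjusted p under 0.05).

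The choroid plexus genes lay lower in both deletion libraries. Library 1 alone is argued against, since the median log2 fold change of the list without it was -1.33. Library size alone as the scale left the median at -2.06, as with TMM factors, so this setting moved nothing and does not decide on scaling. A share of choroid plexus tissue that varied with the dissection remains open. The deletion was directed at excitatory forebrain neurons, while the choroid plexus is an epithelium next to the hippocampus. An effect of the deletion on it would be indirect unless the recombinase also acted there, which was not measured. Ttr spanned 20.2-fold between the libraries of tTA::miR212, larger than its fall in the deletion, but 1.10-fold between the deletion's own controls, so dissection and an effect of the deletion cannot be told apart with 2 libraries per group. The joint loss of the member genes is consistent with either.

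Deletion library 1 had 1047 genes at 0. Lower depth is argued against by its total, 0.997 of the median of the other libraries, and loss of these transcripts with the genotype by the same genes in deletion library 2, whose median log2 ratio to controls was -0.00522. If few distinct molecules stood behind its reads, the share of genes at 0 would follow exp(-expected/k) with about 1 value of k. Over all bins of expected count k varied 7.49-fold, past the bound of 3 set beforehand, but a gene enters the table only with a maximum of at least 91 counts in some library, which removes genes at 0 from the lower bins, so that bound was wrong for them. Over the 5 bins above it k varied 1.11-fold (112.6 to 124.9), though this test followed the first result. Where the other libraries had genes at 0 in these bins, their k also varied little, but few genes stood behind it. Of genes expected at 200 to 300 counts, 0.0827% of 1209 were at 0 in control library 1 and 0.0756% of 1323 in control library 2. The counts expected for these libraries also drew on deletion library 1. Their k was 35.51 to 43.61 in deletion library 2, 30.44 to 34.98 in control library 1 and 24.81 to 34.45 in control library 2. With so few genes, these values cannot show whether a nearly constant k sets library 1 apart, although its k was higher. Few distinct molecules remain a possible account of the zeros that this test cannot decide.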

How the results depend on the processing

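The joint fit of both RefSeq tables and its repeat without the libraries richest in zeros, the fit of all transcripts, the seed test with an estimated correlation, the estimated correlation for lists with a library left out or the block, bounds with a library left out and the block for lists were chosen after seeing the data. The edgeR counts of 0 genes held in each comparison with library size alone, upper-quartile factors, no filter and a mean of at least 50 counts, for tTA::miR212 with all transcripts (0, with 554 at an unadjusted p under 0.05), and in the joint fit. They moved to 5 (deletion) and 39 (tTA::miR132) with DESeq2, to 2 with limma-voom (tTA::miR132) and to 2 in the deletion in the joint fit without deletion library 1 and tTA::miR132 control library 2 (Ttr and Mrpl15). Leaving out 1 library gave 1 to 4527 genes in the deletion, 0 to 111 in tTA::miR132 and 0 to 18 in tTA::miR212. It leaves an arm with 1 library in the RefSeq tables, which is then assumed to vary like the other group. Simulated calls by DESeq2 held many unchanged genes there (73 of 153 and 49 of 148). For the other settings the cause was not tested.

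The calls on lists (1, 1 and 2) all fell to 0 with an estimated correlation, with fry directional and with fry mixed, and leaving out 1 library gave 1 to 3, 0 to 2 and 0 to 3. With both an estimated correlation and 1 library left out, 0 lists were called in the deletion and in tTA::miR132, and 0 to 1 in tTA::miR212 (the immediate early genes, without transgenic library 1). The seed-site difference reversed in the deletion with 8-base sites (0.0404) and against control 7-mers (0.0071), and leaving out 1 library gave -0.0271 to 0.0384, -0.0436 to 0.0095 and 0.0012 to 0.0352. No seed difference passed its test, and for these and the lists the cause was not tested. The estimated correlation of the vesicle list in tTA::miR132 was -0.018, under the set 0.01. Correlated members therefore do not account for the loss of that call. Between the deletion and tTA::miR132, r moved to -0.0015 for genes with at least 50 counts, and leaving out 1 library gave -0.0358 to 0.0179, -0.0276 to 0.0212 (deletion and tTA::miR212) and 0.0043 to 0.111 (both transgenes). Of 232 alternative values for 34 named genes and lists, 186 kept their direction and side of the threshold, 37 came to pass it, 9 ceased to pass it and 0 reversed. The named genes were picked for small p and their groups did not overlap. A reversal with a library left out was therefore hardly possible, and its absence says little about robustness.

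The numbers of the libraries gave no sign of pairing. The deviations of same-numbered libraries correlated by 0.01 in the deletion and in tTA::miR132 and by -0.08, 0.02 and -0.03 in tTA::miR212. With 2 libraries per group the deviations mirror each other and give 1 value for each RefSeq comparison, so a shared day or litter is not excluded. With the number as a block, edgeR called 0 genes in the deletion, 1 in tTA::miR132 (Camk2n1) and 1 in tTA::miR212 (Ptprn2), and the lists called were 1, 1 and 3. The list gained was that of immediate early genes in tTA::miR212 (adjusted p = 0.00268, or adjusted p = 0.651 with an estimated correlation), and with the block and an estimated correlation 0 lists were called in each comparison. The block moved the median of the choroid plexus list in the deletion from -2.06 to -4.17, and the cause was not tested. A single fit of all libraries and the test of one transgene's effect against the other's were not run, and alternatives for normalized values did not apply. The spread between libraries limits the RefSeq comparisons, where simulated 2-fold changes were recovered in 9.38% and 6.15% of genes. Totals of 1299369 to 1544923 counts limit the precision for genes of few counts in the tTA::miR212 table.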

Other observations

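The tests of the female share and of handling, and the adjustment of the test of genes near the locus, were chosen only after the result was seen.

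No list of interneuron or CA pyramidal cell markers passed in tTA::miR212. Of 8 measured interneuron genes 7 lay above 0 (median 0.14, adjusted p = 0.0965), with Calb2 at 0.85 (SE 0.39), while Sst, the somatostatin gene, had -0.28 (SE 0.11). All 5 measured CA1 genes lay below 0 (median -0.04, adjusted p = 0.214), led by Mpped1 (-0.20, SE 0.09), which had -0.56 (SE 0.25) in tTA::miR132. In tTA::miR132 the myelin genes Mal (0.54, SE 0.20) and Mbp (0.24, SE 0.11) lay higher, in a list with a median of 0.17 (adjusted p = 0.653).

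The lower glucocorticoid-responsive genes in tTA::miR212 may reflect the sex of the pooled animals or their state at dissection as well as the transgene or the transactivator. Xist CPM was below all controls in each transgenic library. The transgenic library with the highest Xist, library 2, had a list level of -0.44 relative to the lowest control, farther from controls than the others, but 1 library does not exclude a female share as a cause. Immediate early genes lay lower in the same group (camera, adjusted p = 0.0965), but high in library 1. The sources used here give no handling of the animals apart from genotype, so these explanations cannot be told apart.

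The 10 splits of the 6 libraries of the tTA::miR212 table are too few for a share under 0.05. The real split gave 0 genes past the threshold and the highest other split 0, so all 10 gave as many. At an unadjusted p under 0.05 the real split gave 260 genes and the highest other 438.

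A hypothesis that genes around the Mir132 and Mir212 locus differ between deletion and control animals was tested on the 126 genes within 5 Mb of it. No shift was detected (camera, adjusted p = 0.953 over this set and the 25 lists, median log2 fold change -0.03). A p above the threshold had been set beforehand as evidence against a shift, which was wrong, since it does not exclude a small one. The 95% interval of the mean difference from other genes, -0.29 to 0.22, leaves shifts of 0.2 possible.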
